A study of Mus musculus with 75 samples.

How the data were processed

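Nuclear RNA was measured in nuclei sorted by fluorescence from the nucleus accumbens of male mice that carried a Cre-dependent green fluorescent protein fused to ribosomal protein L10a together with Cre driven by the gene of either the D1 or the D2 dopamine receptor. Per the labels, mice were given saline or cocaine (20 mg/kg, intraperitoneal) on 10 consecutive days, were left undisturbed for 30 days, and were then given 1 challenge of saline or cocaine, and tissue was taken 1 h later. Group names give the receptor line, then the repeated injections, then the challenge, with S for saline and C for cocaine, so that D1_SC is repeated saline with a cocaine challenge in the D1 line. Per the labels' protocols, total RNA from sorted nuclei was purified with a column microprep and made into stranded total RNA libraries with a low-input SMART kit that removes ribosomal sequence after amplification.

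The deposited tables held raw counts and FPKM for 55401 gene identifiers in 75 libraries, and all 75 columns matched a labelled sample. Per the submitters' processing notes, the tools were featureCounts and DESeq2 and the genome build was mm10; versions, aligner, annotation and the strand setting of the counting were not given in the sources used here. The counts deposited by the authors were whole numbers, and the FPKM values deposited by the authors equalled the count divided by the library's total count and by a gene length, scaled to 1000000 counts and 1 kilobase. The length equalled the full gene span, introns included, of GENCODE release M21 (mm10) for 54271 of the 54271 identifiers that could be compared. FPKM served only to read off these lengths, and all tests were run on the counts. Gene symbols and coordinates were taken from the GENCODE M21 annotation, which held 54349 of the identifiers exactly and 55141 without regard to the version suffix. Because the strand setting of the counting was not given, values of genes that overlap another gene, and of members of families with near-identical copies such as ribosomal protein, olfactory receptor and vomeronasal receptor genes, are uncertain.

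Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr by group), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 4 treatment groups of a receptor line were fitted together, 37 D1 libraries over 37721 genes and 38 D2 libraries over 36090 genes, and comparisons across lines used all 8 groups and 75 libraries over 39250 genes. All p values of the gene tests and list tests are two-sided. Log2 changes are those of the edgeR fit, with a standard error (SE) obtained from the size of the change and the test statistic. CPM are counts per 1000000 of the library's total, given as mean ± SD, and "higher in" gives the number of libraries of the first group above the mean of the second. In each line the comparisons were SC minus SS, CS minus SS, CC minus SS, CC minus CS, CC minus SC, and the interaction of the challenge with history, (CC minus CS) minus (SC minus SS). Across lines they were D1 minus D2 in SS, and the difference of the D1 and D2 changes for SC, CS and CC against SS, which makes 16 comparisons in all.

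The main tests, a first set of alternatives and 25 gene lists for this tissue and treatment were fixed before the data were examined. Lists were tested with limma 3.58.1 (camera on voom values, preset correlation between genes of 0.01, adjustment over the lists of a comparison), and again with an estimated correlation. Of the 400 list tests, 197 passed with the preset and 8 with the estimated correlation, and these 8 are named where they occur. The median change of a list comes from the limma fit and stands beside the median of all genes in that fit. The genes that may be named were those with the 10 largest rises and 10 largest falls among the genes that passed, with an average log2 CPM of 1 or more and a conventional symbol, plus up to 4 members of each list that passed, plus fixed markers (Drd1, Drd2, Adora2a, Penk, Tac1 and Pdyn between lines; Fos, Arc, Egr1 and Npas4 for challenge comparisons); where fewer than 3 genes passed, the 5 with the smallest p were taken. Of the genes this rule gave, the text names a part, picked after the values were seen so as to show the gene groups described. The directions of changes in the D1 and D2 lines, and of the challenge response with and without cocaine history, were compared by Pearson's r across genes with a permutation p from 100 shuffles of treatment labels; genes are not independent replicates.

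A quality rule was fixed in advance: a library failed with a total count under its line's median divided by 3, with a number of genes with 10 or more counts over 4 scaled median absolute deviations below the line's median, with a log2 ratio of Drd1 to Drd2 on the other line's side of the midpoint of the line medians, or with a median Spearman correlation to its line over 4 such deviations below the median. Libraries that failed stayed in all main tests. After the counts were seen, an even background was estimated in each library from 1420 olfactory and vomeronasal receptor genes, families expressed in sensory epithelia: their counts per base, carried over all gene spans (with X and Y at 1 copy against 2 of each autosome, as in male mice), gave the share of the library's counts that an even density of reads would account for. Group shares were compared by two-sided exact permutation tests, with adjustment over 10 comparisons. Principal components, correlations and permutation tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

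Alternatives fixed in advance were DESeq2 1.42.0, RLE scaling in edgeR, no filter on low counts, the replicate number as a block, 2 surrogate variables (sva 3.50.0), limma with library weights, libraries that failed the quality rule left out, and a fit of the compared groups alone. Chosen after seeing the data were the background subtracted from the counts, its share as a covariate, the subtraction with failing libraries left out, 4 D1 libraries left out whose ratio of reads per base beside the receptor genes lay on the D2 side (log2 ratio under 0), and each library left out in turn. Total counts per library ranged from 19825 to 34870414. Intervals for single libraries are 95% Wilson intervals, and 3 counts were taken as the most that a count of 0 allows; reads were not collapsed to molecules in these tables as far as the sources used here state, so both cover counting error only.

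The tests were tried on counts simulated from these libraries with 200 genes changed. For D1 SC minus SS, edgeR recovered 38% of genes changed 2-fold and 93% of those changed 4-fold, and called 3 of the unchanged genes among 37265. For D2 CS minus SS these were 20%, 94% and 10 of the unchanged genes among 35698, and for D1 minus D2 in SS 32%, 95% and 6 among 38890. In each of the 3 simulations a list of 20 raised genes passed and 0 of 20 unchanged lists did. The simulated genes varied independently of each other and carried no differences in background between libraries. The few false calls of genes and lists therefore need not hold for the real libraries.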

Results

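Nuclear RNA was compared in 75 libraries of sorted nuclei from the nucleus accumbens of male mice, each library 1 replicate. The D1 line gave 10 SS, 9 SC, 8 CS and 10 CC libraries and the D2 line 9 SS, 9 SC, 10 CS and 10 CC libraries, where the first letter is the repeated injection and the second the challenge (S saline, C cocaine). Total counts had a median of 14893119. They ranged from 12172926 to 24520138 in D1_CC, 4146700 to 26695612 in D1_CS, 651445 to 25320198 in D1_SC and 8736018 to 29845486 in D1_SS. In the D2 line they ranged from 19825 to 24325649 in D2_CC, 19980 to 34870414 in D2_CS, 2040625 to 21805478 in D2_SC and 5331227 to 17808952 in D2_SS. No pair of libraries was identical.

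The receptors that name the lines separated most libraries, but not all. Drd1, the D1 dopamine receptor, stood at 123 ± 67.8 CPM (SD, n = 10) in D1_SS and 32.4 ± 12.8 (n = 9) in D2_SS, and Drd2, the D2 receptor, at 52.4 ± 7.25 and 848 ± 565. Of the 37 libraries labelled D1, 16 held more Drd2 than Drd1, against 0 of the 35 libraries labelled D2 with over 1000000 counts that held more Drd1 than Drd2. The quality rule failed 18 libraries: 3 of D1_CC, 2 of D1_CS, 4 of D1_SC, 2 of D2_CC, 5 of D2_CS, 2 of D2_SC and 0 of each SS group. Depth failed 13 of them, the correlation with the other libraries 10, the receptor ratio 5 and the number of genes 1, some for more than 1 reason. D1_SS 8 and 9 passed but held only 17.5 and 22.3 CPM of Drd1 and 12.2 and 12.6 of Penk. The other D1_SS libraries held 76.9 to 229 of Drd1 and 37.3 to 612 of Penk. Reads per base of genes beside the receptor genes, described with the D1 and D2 difference, gave a ratio on the side of the other line in 4 libraries labelled D1 (D1_CC 4, 9 and 10 and D1_CS 4) and in 0 labelled D2.

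**Figure D1:**
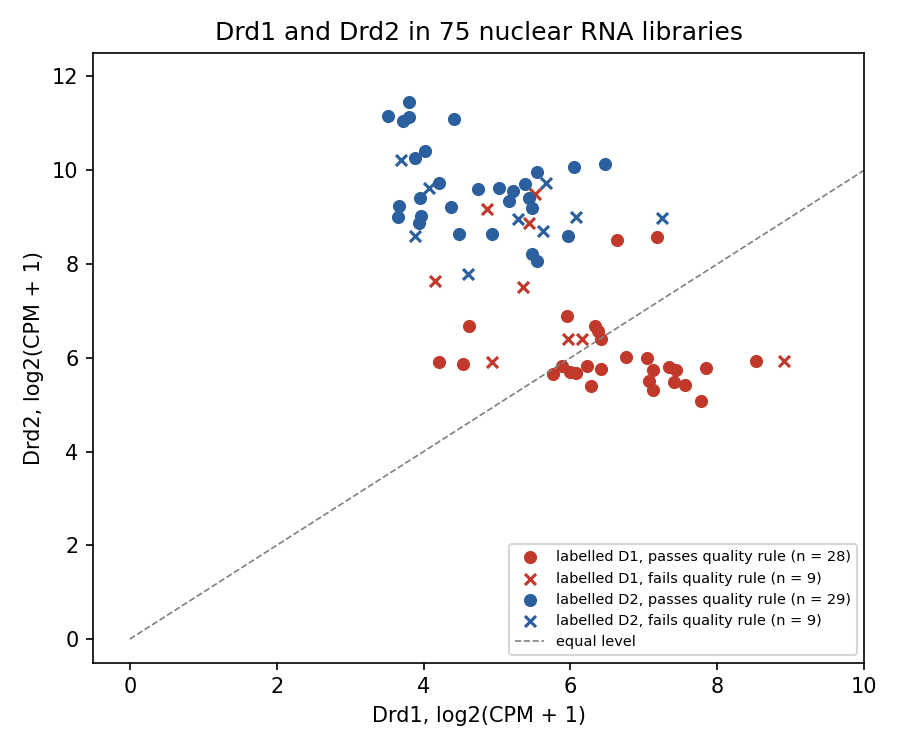
Drd1 (x axis) and Drd2 (y axis), each as log2(CPM + 1), in 75 libraries; colour gives the line on the label, crosses are libraries that fail the quality rule and the dashed line marks equal levels. Of 37 libraries labelled D1, 16 lie above the dashed line. Levels include the even background, which is larger for Drd2 than for Drd1.

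Reads also fell on genes that are silent in brain. Olfactory and vomeronasal receptor genes carried reads in every library with over 1000000 counts, and an even density at their level would account for 3.96% (95% interval 3.87 to 4.06, D1_CC 3) to 69.7% (68.8 to 70.5, D1_CS 7) of a library's counts. This background share was 45.1% ± 11.6 in D1_SS, 22.5% ± 17.7 in D1_SC, 55.7% ± 19.0 in D1_CS and 44.9% ± 21.1 in D1_CC (SD). In the D2 groups it was 43.2% ± 16.8, 33.6% ± 19.6, 34.3% ± 19.8 and 39.8% ± 19.6 in the same order. D1_SC lay 22.6 percentage points below D1_SS (exact permutation p = 0.00548, adjusted p = 0.0548 over 10 comparisons). Among libraries passing the quality rule D1_SC lay 14.9 points below D1_SS (exact p = 0.0932, adjusted p = 0.682). D1_CC lay 22.3 points above D1_SC (exact p = 0.0270, adjusted p = 0.135), and the other 8 comparisons had larger p. The share tracked the first principal component, 56.9% of the variance, across 71 libraries (r = 0.937, rho = 0.972, permutation p = 0.0001 for each, the smallest the permutations can give; adjusted p = 0.000167 over 5 relations). It did so without the 2 farthest libraries (r = 0.934) and within D1 (r = 0.951) and D2 (r = 0.923).

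**Figure D2:**
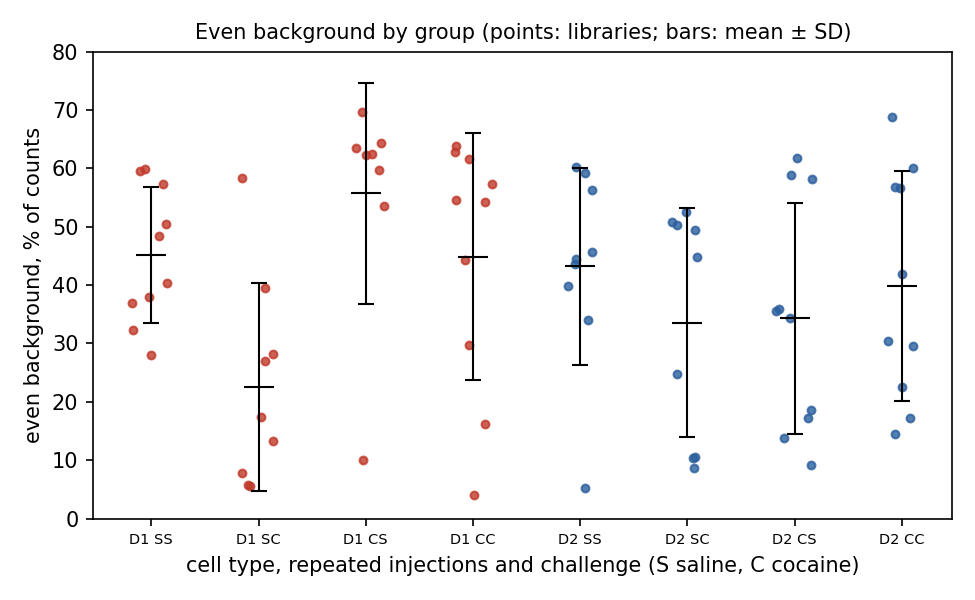
Even background as a percentage of counts (y axis) in each group (x axis); points are libraries and bars mean ± SD. D1_SC has the lowest mean, 22.5%, and D1_CS the highest, 55.7%.

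D1 and D2 nuclei were first compared in the saline groups, the check of the sort. Drd2 (ENSMUSG00000032259.8, mm10 chromosome 9, 49340627 to 49408177) was lower in D1_SS than in D2_SS, with a log2 change of -4.35 ± 0.57 (SE, n = 10 and 9; adjusted p = 2.27e-06; 0 of 10 D1 libraries above the D2 mean). Adora2a, the adenosine receptor of D2 neurons (ENSMUSG00000020178.6, chromosome 10, 75316877 to 75334784), was lower too, at -2.56 ± 0.47 (adjusted p = 0.00411). So was P2ry1, a purine receptor (-2.19 ± 0.45, adjusted p = 0.0265). The 7 measured D2 neuron markers had a median log2 change of -2.58 (all genes 0.02) and passed the list test (adjusted p = 9.17e-56; adjusted p = 3.39e-10 with an estimated correlation), with 2 lower among all genes and 7 adjusted over the list alone. The 9 D1 neuron markers had a median of 0.97 (adjusted p = 7.53e-23; adjusted p = 8.2e-06 with an estimated correlation), with 1 higher among all genes (Sfxn1) and 7 adjusted over the list alone. Pdyn (2.02 ± 0.50, adjusted p = 0.333), Drd1 (1.84 ± 0.51, adjusted p = 1.00, higher in 8 of 10), Tac1 (1.26 ± 0.49) and Penk (-1.88 ± 0.57), the neuropeptide and receptor genes that also part these cells, did not pass.

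In all, 10 of 39250 genes passed, 5 higher and 5 lower in D1, and 8 of the 10 were Drd2 or genes beside a receptor gene. Ankk1 (ENSMUSG00000032257.6, chromosome 9, 49415194 to 49427021) and Ttc12 lay 7016 and 28785 bases from Drd2 and were lower in D1 (-2.55 ± 0.38, adjusted p = 4.78e-05, and -1.79 ± 0.30, adjusted p = 0.00066; Ttc12 had adjusted p = 0.0672 with RLE scaling). The 5 higher in D1 were Sfxn1, a mitochondrial serine carrier (ENSMUSG00000021474.9, chromosome 13, 54071869 to 54108342; 101 ± 19.5 against 29.5 ± 5.84 CPM, higher in 10 of 10), and 4 unnamed genes, Gm18974, E130119H09Rik, Gm34557 and Gm48550, named here after their values were seen. All 5 lay within 160327 bases of Drd1, between 53888627 and 54108342 on chromosome 13, and their log2 changes spanned only 1.63 to 1.70 (Sfxn1 1.65 ± 0.31, adjusted p = 0.00599). Past this stretch the log2 change was 1.44 ± 0.42 at Gm18473, the next gene, and fell off to 0.22 ± 0.22 at Hrh2 beyond it and to 0.45 ± 0.33 at Gm48548 on the other side (adjusted p = 1.00 for each). Among 38276 runs of 5 neighbouring genes in the genome, the run with the highest mean, 1.70, held Drd1 and the run with the lowest, -1.98, held Drd2.

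**Figure D3:**
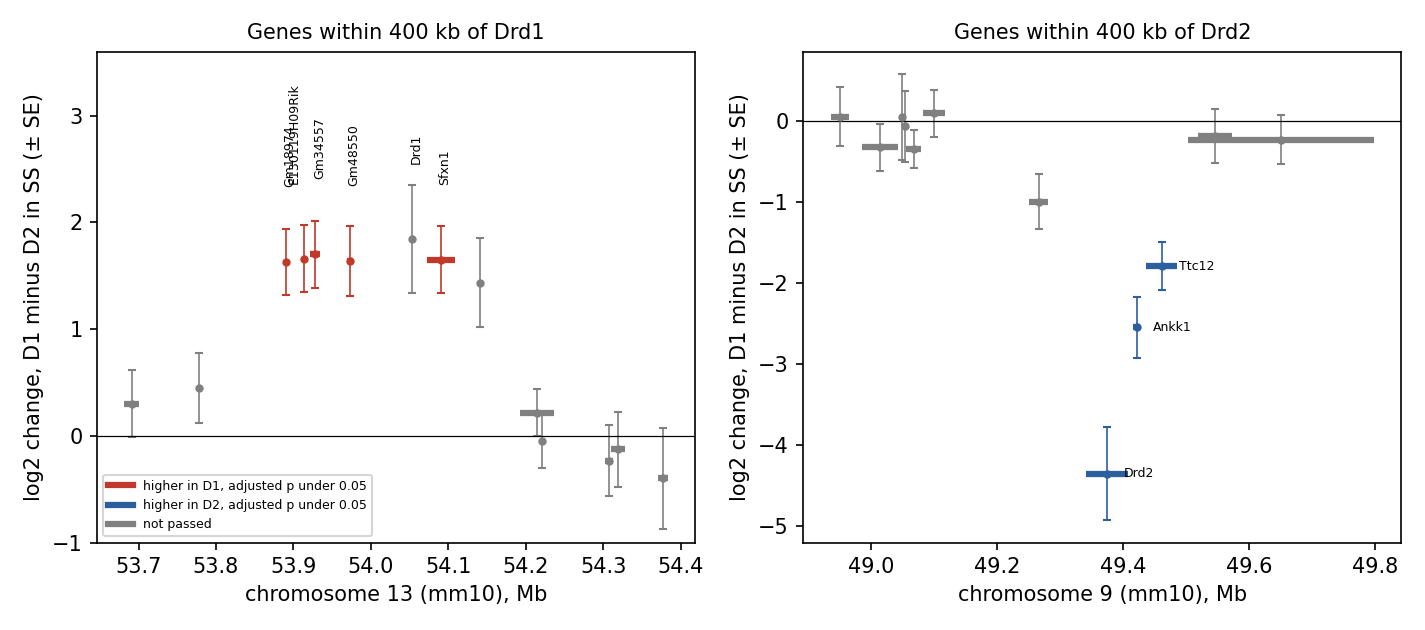
Log2 change of D1 minus D2 in SS (y axis, ± SE) against position in mm10 (x axis, Mb) for genes within 400 kb of Drd1 and of Drd2; thick lines are gene spans, and colour marks genes that passed. The 5 genes higher in D1 and Drd1 itself lie on a plateau from 1.63 to 1.84.

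The density of the 4 unnamed genes and of Ankk1 with Ttc12 was also read in each library, a measure chosen after seeing the data. Over the library's own background, the 4 genes beside Drd1 stood at a median of 5.33 times in D1_SS (4.59 to 8.15) and 1.77 times in D2_SS (1.25 to 4.31), and Ankk1 with Ttc12 at 1.75 (1.45 to 2.47) and 6.48 (4.91 to 38.1). The log2 ratio of the 4 genes to Ankk1 and Ttc12 ran from 0.12 to 2.84 in 32 libraries labelled D1 and from -3.12 to -0.51 in 35 labelled D2. It ran from -1.89 to -0.44 in the 4 others labelled D1, and 4 libraries had too few counts to read. Ribosomal protein genes (88 measured, 39 with log2 changes above 0 and 49 below) had a median of -0.46 in D1 minus D2 (adjusted p = 1.19e-20; adjusted p = 0.52 with an estimated correlation).

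A first cocaine challenge after repeated saline, SC minus SS, asked what acute cocaine does within 1 h. In D1 nuclei the activity-regulated transcription factor genes Nr4a3 (ENSMUSG00000028341.9, chromosome 4, 48045153 to 48086447; 68.4 ± 33.7 against 35.4 ± 6.24 CPM, n = 9 and 10), Nr4a1 and Fosl2 rose, by log2 changes of 1.55 ± 0.36, 1.36 ± 0.37 and 1.17 ± 0.30 (adjusted p = 0.00577, 0.0149 and 0.00972; higher in 8, 5 and 7 of 9). The rapid immediate early genes (22 measured, 21 above 0) had a median of 0.46 against -0.21 for all genes (adjusted p = 1.74e-04; adjusted p = 0.372 with an estimated correlation), with 4 higher among all genes and 5 adjusted over the list alone. The classical members did not pass: Egr1 0.74 ± 0.50 (adjusted p = 0.302), Arc 0.61 ± 0.47 (adjusted p = 0.368), Fos 0.46 ± 0.44 (adjusted p = 0.475; 5.38 ± 6.25 against 5.31 ± 2.34 CPM) and Npas4 0.11 ± 0.34 (adjusted p = 0.852). The fit uses TMM scaling and the CPM do not. For D1 SC minus SS the fitted changes were larger than the mean CPM show, as for Nr4a3 and Fos here and for Per1 and Pde4b below. The part of these rises that comes from scaling was not separated. Of 23 delayed activity-regulated genes 3 were higher and 5 adjusted over the list alone (median 0.10, adjusted p = 0.029; adjusted p = 0.372 with an estimated correlation), among them the synaptic scaffold gene Homer1 (1.49 ± 0.38) and Inhba (1.13 ± 0.36). Of 13 feedback regulators of MAP kinase, 6 were higher and 7 adjusted over the list alone (median 0.62, adjusted p = 1.52e-04; adjusted p = 0.372 with an estimated correlation), with Spred2 at 1.24 ± 0.28.

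Clock and signalling genes rose with them in D1_SC. Per1, a core clock gene (ENSMUSG00000020893.17, chromosome 11, 69095217 to 69109960), rose by 1.48 ± 0.38 (adjusted p = 0.011; 55.9 ± 15.4 against 30.2 ± 8.61 CPM, higher in 8 of 9), Per2 by 1.13 ± 0.28 and Npas2 by 1.55 ± 0.33 (higher in 9 of 9). The 17 clock genes had a median of 0.51 (adjusted p = 3.53e-05; adjusted p = 0.372 with an estimated correlation), with 6 higher and 8 adjusted over the list alone. Pde4b, which breaks down cAMP (ENSMUSG00000028525.16, chromosome 4, 102087543 to 102607259), rose by 1.67 ± 0.31 (adjusted p = 0.00293; 1220 ± 464 against 629 ± 86.8 CPM, higher in 8 of 9). Of 25 dopamine receptor and cAMP signalling genes 13 were higher and 16 adjusted over the list alone, among them the D3 receptor gene Drd3 (1.39 ± 0.27). Their median was 0.57 (adjusted p = 6.6e-11, or adjusted p = 0.299 with an estimated correlation). Drd2, which belongs to the D2 neuron markers and not to this list, rose by 1.56 ± 0.49. Drd2 was highest in D1_SC 5 at 200 CPM (95% interval 168 to 237) and stood at 180 in the next, both failing libraries. The 7 D2 neuron markers did not pass as a list (median 0.45 against -0.21, adjusted p = 0.0793). Of these, 2 were higher among all genes and 3 adjusted over the list alone. Of 13 markers of medium spiny neurons 7 were higher and 10 adjusted over the list alone, with Pde10a and Meis2 at 1.35 each (median 0.90, adjusted p = 9.52e-07; adjusted p = 0.372 with an estimated correlation).

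Lists of synaptic and chromatin genes were higher as well in D1_SC. The list tests set members against all genes tested, which include silent receptor genes. The mean background share was 22.5% in D1_SC and 45.1% in D1_SS. For the lists of D1 SC minus SS here and above, a response to cocaine cannot be told apart from this lower background. Of 21 glutamate receptor genes 10 were higher and 13 adjusted over the list alone (median 0.63, adjusted p = 1.46e-06; adjusted p = 0.299 with an estimated correlation), with Grm7 at 1.65 ± 0.33 and Gria1 at 1.63 ± 0.37. Of 43 DNA methylation and histone modifying enzymes 25 were higher and 29 adjusted over the list alone (median 0.69, adjusted p = 8.1e-12; adjusted p = 0.299 with an estimated correlation), with the methyltransferase gene Kmt2d at 1.66 ± 0.32 (higher in 9 of 9). Of 87 axon guidance and adhesion genes 24 were higher and 34 adjusted over the list alone (median 0.32, adjusted p = 1.43e-06; adjusted p = 0.299 with an estimated correlation), and of 92 potassium channel genes 24 were higher and 1 lower, or 29 and 3 adjusted over the list alone (median 0.24, adjusted p = 8.33e-05; adjusted p = 0.299 with an estimated correlation). D1_SC 2, 4 and 9 held 64.1% (95% interval 64.0 to 64.1), 63.2% (63.1 to 63.2) and 61.7% (61.6 to 61.7) of their counts in genes over 100 kb, against a median of 50.8% in D1_SS.

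Single markers of other cells rose, some of them through 1 library, while the lists of astrocyte, oligodendrocyte and glutamatergic neuron markers did not pass (adjusted p = 0.134, 0.0768 and 0.480). The myelin gene Mobp (1.69 ± 0.41) and the astrocyte transporter gene Slc1a2 (1.54 ± 0.29) were higher, and Slc17a7, the vesicular transporter of cortical neurons, rose by 1.57 ± 0.52. Mobp stood at 192 CPM in D1_SC 5 and 75.5 in the next library, with medians of 22.9 in SC and 21.3 in SS. D1_SC 5, with 651445 counts, held 388 CPM (95% interval 343 to 439) of the gut peptide gene Guca2b against 2.03 in the next library. It also held the highest Hepacam, 669 against 43.0 CPM, and the highest Hdhd5, 1062 against 36.6 (5.38 ± 0.99, 3.29 ± 0.65 and 3.06 ± 0.59 in the fit; Guca2b turned to -0.50 without failing libraries and Hepacam to -0.0159 in limma with library weights). Slc17a7 stood at 129 CPM in D1_SC 7 and 36.7 in the next. Lower genes included Ttr, the transthyretin of choroid plexus (-2.06 ± 0.68, adjusted p = 0.0407; 3.12 ± 4.90 against 19.0 ± 31.2 CPM), and the silent receptor genes Vmn1r172 (-1.39 ± 0.39) and Olfr1496 (-1.52 ± 0.44), beside the lower background share of D1_SC. Ttr stood at 88.0 CPM in D1_SS 6 and 67.0 in the next SS library, with medians of 1.66 in SC and 4.38 in SS. In all 4277 of 37721 genes passed, 3659 higher and 618 lower (3369 and 2282 in DESeq2), and leaving out 1 library gave from 459 (without D1_SC 2) to 10348 (without D1_SC 6). Without the libraries that failed the quality rule, 4 of 9 in D1_SC, 0 passed in edgeR (Nr4a3 1.39, adjusted p = 0.189; Per1 0.96; Pde4b 0.98), and with the background subtracted 373 did.

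In D2 nuclei no gene passed for SC minus SS. The early genes Fos (0.31 ± 0.43), Egr1 (0.25), Arc (-0.24) and Npas4 (-0.26) had adjusted p of 0.988 or more. The 21 rapid immediate early genes as a list had a median of 0.19 against -0.11 for all genes (adjusted p = 0.00602; adjusted p = 0.494 with an estimated correlation; adjusted p = 0.15 without failing libraries). Axon guidance and adhesion genes (87 measured, 67 above 0, median 0.15) and potassium channel genes (92 measured, 60 above 0, median 0.08) passed the list test with both correlations. Their adjusted p were 4.46e-09 and 7.73e-05 with the preset and 0.00244 and 0.0345 with the estimated correlation. D2_SC 3, 4 and 7 held 60.2%, 61.6% and 61.4% of their counts in genes over 100 kb. The median in D2_SS was 51.8%, with 59.0% in D2_SS 9. Whether these libraries carry the changes of these lists was not tested. Ribosomal protein genes (87 measured, 84 below 0) had a median of -0.82 (adjusted p = 4.47e-40; adjusted p = 0.133 with an estimated correlation), with 0 lower among all genes and 21 adjusted over the list alone. Respiratory chain genes (82 measured) had one of -0.50 (adjusted p = 3.73e-18; adjusted p = 0.329 with an estimated correlation). The MAP kinase feedback regulators (13 measured, median 0.22, adjusted p = 2.54e-04) and DNA methylation and histone modifying enzymes (43 measured, median 0.24, adjusted p = 2.3e-10) lost their call (adjusted p = 0.329 and 0.18 with an estimated correlation). The smallest p belonged to Rpl35, of the large ribosomal subunit (-1.54 ± 0.41, 0 of 9 above the SS mean), and Cib2 (2.03 ± 0.54, with 202 CPM in D2_SC 2 and 23.0 in the next), each with adjusted p = 0.647. edgeR called 0 of 36090 genes (1914 at unadjusted p under 0.05), DESeq2 0 and limma with library weights 4892.

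The D1 and D2 responses to the first challenge differed in 11 genes, all higher in D1. Of the genes the naming rule allows, Guca2b differed by 5.36 ± 1.12 (adjusted p = 0.0369), with the counts of D1_SC 5 behind it (-0.72 in DESeq2), while Hdhd5 (2.84 ± 0.67) and Stx1a, a synaptic fusion protein gene (2.49 ± 0.60), had adjusted p = 0.0978. As lists, the rapid immediate early genes (22 measured, median 0.58 against -0.03, adjusted p = 3.83e-04) and ribosomal protein genes (88 measured, median 0.69, adjusted p = 1.7e-10) were higher in D1, each with adjusted p = 0.446 with an estimated correlation. The changes of the lines had r = 0.563 across 35997 genes (permutation p = 0.218), and genes are not independent replicates. Without failing libraries 0 genes differed, and DESeq2 called 0.

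**Figure D4:**
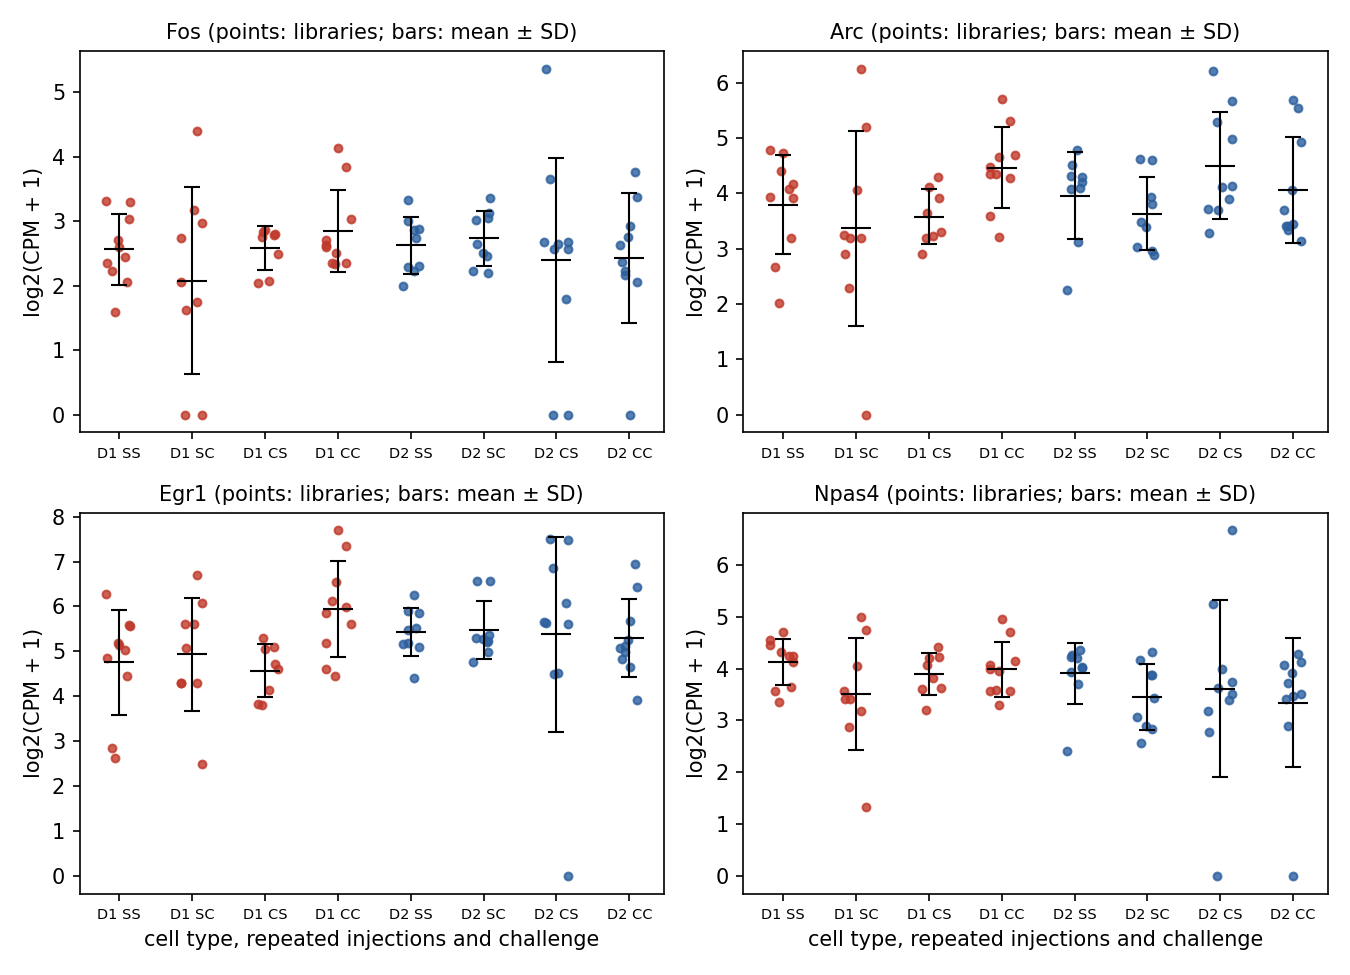
Fos, Arc, Egr1 and Npas4 as log2(CPM + 1) (y axis) in the 8 groups (x axis); points are libraries and bars mean ± SD. Egr1 has its highest group mean in D1_CC, 77.6 CPM.

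Withdrawal was read from CS minus SS, repeated cocaine followed 30 days later by a saline challenge. In D1 nuclei ribosomal protein genes (86 measured, 84 below 0) had a median of -0.75 against 0.01 for all genes, and respiratory chain genes (84 measured) one of -0.64 (adjusted p = 1.49e-26 and 2.2e-26; adjusted p = 0.581 for each with an estimated correlation), with 0 ribosomal genes lower among all genes and 50 adjusted over the list alone. Medium spiny neuron markers (13 measured, median -0.41, adjusted p = 2.74e-05), heat shock genes (11 measured, median -0.57, adjusted p = 0.00631) and oligodendrocyte markers (10 measured, median -0.26, adjusted p = 0.00864) were lower as lists. Each of these 3 had adjusted p = 0.581 with an estimated correlation. No single gene passed: Rpl36 stood at -1.91 ± 0.57 with 0 of 8 libraries above the SS mean (adjusted p = 1.00). Ttr stood at -2.24 ± 0.67 (adjusted p = 1.00), a fall that D1_SS 6 (88.0 CPM) and the next library (67.0) carried, since its median was 5.08 in CS and 4.38 in SS. edgeR called 0 genes (1204 at unadjusted p under 0.05), DESeq2 0 and limma with library weights 16547. The background share was 10.6 points higher in D1_CS than in D1_SS (exact p = 0.160).

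In D2 nuclei 31 genes were higher in CS than in SS, and the largest rises came from single shallow libraries. D2_CS 4, with 1367040 counts, held 321 CPM (95% interval 293 to 353) of the homeobox gene Hoxc12 against 5.80 in the next library, and 656 of Wfdc18, 339 of Hoxc13, 263 of Hoxa7, 254 of C1ql4 and 98.0 of Cox7a1. Their log2 changes ran from 7.17 ± 1.15 for Hoxc12 (adjusted p = 0.00498) and 6.77 ± 1.13 for Wfdc18 down to 4.01 ± 0.82 for Cox7a1. D2_CS 3 held 155 CPM of Ly6a, a vascular surface antigen (4.29 ± 0.84), and 142 of Nfkbia, the inhibitor of NF-kappa-B (3.12 ± 0.64, adjusted p = 0.0268). D2_CS 6, with 26297 counts, held 13005 CPM of Plcd3 (6.15 ± 1.12) against 17.9 in the next. As lists, markers of vascular cells (7 measured, median 0.70 against 0.07, adjusted p = 0.00214), oligodendrocyte precursors (6 measured, 0.47, adjusted p = 0.00409) and astrocytes (10 measured, 0.35, adjusted p = 0.0132) were higher. Each had adjusted p = 0.525 with an estimated correlation, with 0 members among all genes and 3, 1 and 2 adjusted over the list alone. Oligodendrocyte markers (10 measured, 0.34, adjusted p = 0.0169) and rapid immediate early genes (21 measured, 0.34, adjusted p = 0.0174) had adjusted p = 0.597 and 0.611 with an estimated correlation. Ribosomal protein genes had a median of -0.54 (87 measured, adjusted p = 3.25e-42; adjusted p = 0.46 with an estimated correlation) and respiratory chain genes one of -0.28 (82 measured, adjusted p = 2.21e-15; adjusted p = 0.525 with an estimated correlation). Without the failing libraries, 5 of 10 in D2_CS, edgeR called 0 genes and Hoxc12 turned to -0.15; Plcd3 turned to -0.0249 in DESeq2 and Nfkbia to -0.66 in limma with library weights.

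The withdrawal changes of the lines differed in 35 genes, all lower in D1, among them Hoxc12 (-7.21 ± 1.19), Wfdc18 (-6.72 ± 1.13), Plcd3 (-6.23 ± 1.07) and Nfkbia (-3.67 ± 0.77, adjusted p = 0.0219), the genes of those D2_CS libraries. Hoxc12 turned to 0.18 without failing libraries, Wfdc18 and Plcd3 to 0.24 and 0.0854 in DESeq2, and Nfkbia to 0.19 in limma with library weights. Vascular markers (7 measured, median -0.74 against -0.16, adjusted p = 0.0166) and oligodendrocyte markers (10 measured, median -0.79, adjusted p = 0.00244) differed as lists, each with adjusted p = 0.5 with an estimated correlation. Without failing libraries 0 genes differed. Across 35997 genes the changes of the lines had r = -0.0563 (permutation p = 0.891).

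Cocaine after cocaine was compared with saline throughout in CC minus SS. In D1 nuclei markers of D2 neurons were higher in CC (7 measured, median 1.28 against -0.04, adjusted p = 2.82e-09; adjusted p = 0.0143 with an estimated correlation), with 0 among all genes and 5 adjusted over the list alone. Drd2 stood at 234 ± 256 against 52.4 ± 7.25 CPM (2.23 ± 0.49, higher in 7 of 10), Adora2a at 1.68 ± 0.39 and P2ry1 at 1.41 ± 0.37. Without the 4 libraries whose receptor region ratio lay on the D2 side, 3 of them D1_CC, Drd2 came to 1.24 and Adora2a to 1.38. The median of Drd2 was 60.02 CPM in CC and 53.19 in SS. D1_CC 7, which stayed in, held 379.5 CPM. D1_CC 1, 2, 3, 5, 6 and 8 held 38.8 to 60.3, against 41.4 to 64.2 in D1_SS. In CPM the rise of Drd2 therefore came from D1_CC 4, 7, 9 and 10. Adora2a was also high in D1_CC 1 and 3 (59.3 and 66.5 CPM, against at most 45.1 in D1_SS). Rapid immediate early genes (22 measured, median 0.59, adjusted p = 4.46e-10; adjusted p = 0.195 with an estimated correlation) had 0 higher among all genes and 11 adjusted over the list alone. Egr1, an activity-induced transcription factor, stood at 77.6 ± 60.9 against 33.1 ± 20.8 CPM (1.68 ± 0.50, higher in 8 of 10), Arc at 1.01 ± 0.46, Fos at 0.80 ± 0.43 and Npas4 at 0.21 ± 0.33. D1_CC 3, which failed the quality rule, held the most Egr1, 206 CPM (95% interval 199 to 213), with 162 in the next and medians of 59.7 in CC and 32.9 in SS. It also held the most Fos, 16.6 CPM (14.8 to 18.6), with 13.4 in the next and medians of 5.16 and 4.78. D1_CC 3 failed only by its correlation with the other libraries and had the lowest background share, 3.96%. D1_CC 1, the next for Egr1 and Fos, had 16.2%. A lower share can raise the CPM of expressed genes, and that part of these levels was not separated. All 17 clock genes lay above 0 (median 0.38, adjusted p = 9.1e-07; adjusted p = 0.276 with an estimated correlation), with Bhlhe40 at 1.66 ± 0.42. Bhlhe40 stood at 60.4 CPM (56.8 to 64.1) in D1_CC 3 and 53.0 in the next, with medians of 15.1 in CC and 9.92 in SS.

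Heat shock genes (11 measured, median 0.71, adjusted p = 9.31e-08), delayed activity-regulated genes (23 measured, 0.33, adjusted p = 6.38e-05) and neuropeptide genes (15 measured, 0.33, adjusted p = 6.77e-05) were also higher as lists in D1_CC, with 5, 2 and 4 members adjusted over the list alone and 0 among all genes. Their calls were lost with adjusted p = 0.192, 0.192 and 0.232 with an estimated correlation. Ribosomal protein genes (86 measured, median 0.53, adjusted p = 4.36e-15) and respiratory chain genes (84 measured, 0.39, adjusted p = 6.73e-13) each had adjusted p = 0.331 with an estimated correlation. D1_CC 1 and 3 held 38.6% and 34.1% of their counts in genes over 100 kb, against a median of 50.8% in D1_SS. Mitochondrial genes held 0.446% and 0.327% there, against a median of 0.135%. Whether these libraries carry the list changes was not tested. Ttr stood at -2.37 ± 0.62 through few SS libraries (88.0 CPM in D1_SS 6 and 67.0 in the next; median 4.48 in CC and 4.38 in SS). No gene of D1 passed (the smallest adjusted p was 0.695): edgeR called 0 genes (2627 at unadjusted p under 0.05), DESeq2 0 and limma with library weights 48.

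In D2 nuclei CC minus SS went the other way for the same metabolic lists. Both lists were also lower in D2 for SC and CS minus SS, and these comparisons all share the same D2_SS libraries. Mitochondrial genes held a median of 0.184% of counts in D2_SS and 0.0610% in D2_CC, with 1.77% in D2_SS 4. A trait of the D2_SS libraries cannot be told apart from a response in CC minus SS. Ribosomal protein genes (87 measured, 84 below 0) had a median of -0.88 against 0.06 for all genes (adjusted p = 5.33e-101; adjusted p = 0.0122 with an estimated correlation) and respiratory chain genes (82 measured, 77 below 0) one of -0.54 (adjusted p = 1.24e-56; adjusted p = 0.0233 with an estimated correlation). Axon guidance and adhesion genes (87 measured, 63 above 0) had a median of 0.16 (adjusted p = 2.72e-05; adjusted p = 0.0233 with an estimated correlation). Heat shock genes (11 measured, -0.44, adjusted p = 0.00277) and oligodendrocyte markers (10 measured, 10 below 0, -0.29, adjusted p = 0.00328) had adjusted p = 0.58 and 0.611 with an estimated correlation. Single genes did not pass: Rpl35 stood at -1.26 ± 0.40, the mitochondrial import gene Timm8b at -1.35 ± 0.43, the actin-binding Tmsb4x at -1.40 ± 0.42, Fos at 0.15, Arc at 0.01, Egr1 at -0.03 and Npas4 at -0.24. Soga3 (3.44 ± 0.78) rested on 18714 CPM in D2_CC 10, a library of 19825 counts, and Ttr (-2.79 ± 0.82) on 188 CPM in D2_SS 3 against 5.63 in the next. edgeR called 0 genes (380 at unadjusted p under 0.05), DESeq2 0 and limma with library weights 8423.

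The lines were set against each other for CC minus SS by the test of the difference. Ribosomal protein genes (88 measured, median 1.40 against -0.11, adjusted p = 6.55e-52), respiratory chain genes (86 measured, 0.96, adjusted p = 8.38e-33), heat shock genes (11 measured, 1.18, adjusted p = 1.42e-06) and D2 neuron markers (7 measured, 1.22, adjusted p = 1.01e-05; 0 among all genes and 4 adjusted over the list alone) were higher in D1. Each had adjusted p = 0.178 with an estimated correlation. Rapid immediate early genes had a median of 0.34 (22 measured, adjusted p = 9.85e-04; adjusted p = 0.49 with an estimated correlation). Adora2a (2.04 ± 0.63) and Soga3 (-3.04 ± 0.82) had adjusted p = 0.82. edgeR called 0 genes (2368 at unadjusted p under 0.05), DESeq2 0 and limma with library weights 19. The changes of the lines had r = -0.456 over 35997 genes (permutation p = 0.129; r = -0.511 with permutation p = 0.0198 without failing libraries).

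A challenge in mice with a cocaine history was read from CC minus CS. In D1 nuclei Actb, cytoplasmic actin (ENSMUSG00000029580.14, chromosome 5, 142903115 to 142906754), rose by 2.82 ± 0.61 (343 ± 277 against 70.5 ± 19.4 CPM, n = 10 and 8; adjusted p = 0.017, higher in 10 of 10). Actg1 rose by 2.95 ± 0.66, the chaperone gene Hsp90aa1 by 2.71 ± 0.59 and Hspa8 by 2.41 ± 0.55. Ribosomal protein genes rose in 63 of 86 measured and in 82 adjusted over the list alone (median 1.30 against -0.09, adjusted p = 2.35e-27; adjusted p = 0.285 with an estimated correlation), with Rpl15 at 2.54 ± 0.60. Respiratory chain genes rose in 60 of 84 and in 72 adjusted over the list alone (median 1.07, adjusted p = 3.33e-25; adjusted p = 0.285 with an estimated correlation), with Ndufb10 at 2.67 ± 0.60 and Atp5b at 2.53 ± 0.57. Heat shock genes rose in 8 of 11 among all genes and in 8 adjusted over the list alone (median 1.22, adjusted p = 2.11e-06; adjusted p = 0.285 with an estimated correlation). Rapid immediate early genes rose in 9 of 22 and in 12 adjusted over the list alone (median 0.57, adjusted p = 2.11e-06; adjusted p = 0.285 with an estimated correlation), with Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984) at 2.11 ± 0.55 (adjusted p = 0.0179, higher in 8 of 10), Jun at 2.09 ± 0.51 and Fosb at 1.70 ± 0.44. Arc (1.46 ± 0.50, adjusted p = 0.0606), Fos (0.90 ± 0.46, adjusted p = 0.307) and Npas4 (0.50 ± 0.35, adjusted p = 0.558) did not pass. Clock genes rose in 6 of 17 and in 10 adjusted over the list alone (median 0.66, adjusted p = 9.03e-06; adjusted p = 0.285 with an estimated correlation), with the repressors Nr1d1 at 2.07 ± 0.48 and Bhlhe40 at 2.02 ± 0.46.

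Of 13 medium spiny neuron markers 3 rose in D1 CC minus CS and 6 adjusted over the list alone (median 0.73, adjusted p = 3.73e-06; adjusted p = 0.285 with an estimated correlation), with Ppp1r1b, which encodes DARPP-32, at 2.23 ± 0.55. The opioid peptide genes Pdyn (2.14 ± 0.59) and Penk (2.09 ± 0.64) and the G protein regulators Rgs4 (2.27 ± 0.56) and Rgs2 (2.20 ± 0.54) rose. Of 7 D2 neuron markers 2 rose and 4 adjusted over the list alone (median 0.74, adjusted p = 0.0129; adjusted p = 0.285 with an estimated correlation). Penk was highest in D1_CC 4 at 1328 CPM (95% interval 1307 to 1348), and without the 4 libraries with a ratio on the D2 side it came to 2.27 (adjusted p = 0.0463). Of 10 oligodendrocyte markers 4 rose among all genes and 4 adjusted over the list alone (median 0.41, adjusted p = 0.00122; adjusted p = 0.285 with an estimated correlation). Mif, Apoe and Rhob rose by 2.93, 2.86 and 2.84. Among 11 lower genes were the nuclear RNA Neat1 (-0.73 ± 0.23, 0 of 10 above the CS mean) and Clec2e (-1.71 ± 0.54; 43.6 CPM in D1_CS 3 and 7.72 in the next). In all 3134 genes passed, 3123 higher; 0 did without failing libraries, with the background subtracted, or without either D1_CC 1 or D1_CC 3. These 2 libraries held 38.6% (95% interval 38.6 to 38.6) and 34.1% (34.1 to 34.1) of their counts in genes over 100 kb and 0.446% (0.443 to 0.449) and 0.327% (0.324 to 0.330) in mitochondrial genes, against 51.1 to 60.1% and 0.0231 to 0.116% in D1_CS.

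In D2 nuclei 91 genes were lower in CC than in CS and 0 higher. Wfdc18 (-6.90 ± 1.13, adjusted p = 0.0036), Hoxc12 (-6.37 ± 1.09), Plcd3 (-5.88 ± 1.08) and Nfkbia (-3.52 ± 0.65), which single D2_CS libraries carried, fell. So did Kmt2b (-2.36 ± 0.55), with 719 CPM in D2_CS 4 and 53.6 in the next, and the potassium channel gene Kcnd1 (-2.14 ± 0.47), with 94.4 and 37.3. Limma with library weights turned Wfdc18 (0.0659), Hoxc12 (0.19), Kmt2b (0.11) and Kcnd1 (0.0739), and Plcd3 turned without failing libraries (0.17). Oligodendrocyte markers (10 measured, median -0.58 against -0.02, adjusted p = 6.53e-07) and D1 neuron markers (9 measured, -0.51, adjusted p = 6.38e-05) were lower as lists. Each had adjusted p = 0.375 with an estimated correlation, with 0 among all genes and 3 and 4 adjusted over the list alone. Vascular markers (7 measured, -0.70, adjusted p = 0.0061) and ribosomal protein genes (87 measured, -0.33, adjusted p = 1.06e-08) had adjusted p = 0.524 and 0.539 with an estimated correlation. The early genes stood at -1.05 ± 0.44 for Egr1, -0.97 for Fos, -0.76 for Arc and -0.41 for Npas4, with adjusted p of 0.477 or more. Without failing libraries 0 genes passed.

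History was read from CC minus SC, repeated cocaine against repeated saline before the same challenge; it shares its SC libraries with SC minus SS. In D1 nuclei the peptide genes Penk (2.30 ± 0.62, adjusted p = 0.0145; 646 ± 468 against 123 ± 112 CPM, higher in 10 of 10) and Npy (1.54 ± 0.43, higher in 10 of 10), Hsp90aa1 (1.81 ± 0.54), Actg1 (1.91 ± 0.60) and Adora2a (1.22 ± 0.40) were higher in CC. Limma with library weights turned Npy (-0.16), Hsp90aa1 (-0.26) and Actg1 (-0.11). Without the 4 libraries with a ratio on the D2 side, Penk came to 2.06 (adjusted p = 0.0625) and Adora2a to 0.73 (adjusted p = 0.319). Grm7 (-1.78 ± 0.33), Pde4b (-1.55 ± 0.31, adjusted p = 0.00216), Npas2 (-1.48 ± 0.33), Drd3 (-1.31 ± 0.27) and Homer1 (-1.25 ± 0.38) fell. The potassium channel gene Kcnd2 (-1.86 ± 0.39), Slc17a7 (-2.08 ± 0.52), and Guca2b (-5.74 ± 1.01) and Hepacam (-3.23 ± 0.65), which D1_SC 5 carried, fell too (Guca2b turned to 0.18 without failing libraries). Glutamate receptor genes fell in 8 of 21 and in 11 adjusted over the list alone (median -0.55 against 0.21, adjusted p = 1.88e-07), and axon guidance and adhesion genes in 18 of 87, or 20 with 1 higher adjusted over the list alone (median -0.25, adjusted p = 4.66e-07). Each of these lists had adjusted p = 0.211 with an estimated correlation. DNA methylation and histone modifying enzymes fell in 7 of 43 and in 16 adjusted over the list alone (median -0.44, adjusted p = 1.65e-08; adjusted p = 0.61 with an estimated correlation), and 3 of 86 ribosomal protein genes rose (median 0.77, adjusted p = 1.05e-04; adjusted p = 0.774 with an estimated correlation). In all 3955 genes passed, 990 higher and 2965 lower; 0 did without failing libraries, 1957 did without the 4 libraries with a ratio on the D2 side, RLE scaling gave 1449 higher and 2605 lower, and DESeq2 4283 and 3292.

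In D2 nuclei CC minus SC lowered 3 lists and no single gene. Clock genes (17 measured, 16 below 0, median -0.22 against 0.17, adjusted p = 1.42e-06), dopamine receptor and cAMP signalling genes (25 measured, -0.29, adjusted p = 3.1e-11) and DNA methylation and histone modifying enzymes (43 measured, -0.25, adjusted p = 9.51e-13) were lower, each with adjusted p = 0.278 with an estimated correlation. Soga3 stood at 2.99 ± 0.77 (adjusted p = 0.954) and Olig1, a factor of the oligodendrocyte lineage, at -3.88 ± 0.86 (adjusted p = 0.569). Olig1 stood at 87.5 CPM (76.9 to 99.5) in D2_SC 1 and 67.1 in the next, both failing libraries, with medians of 1.34 in CC and 1.94 in SC. By method, edgeR called 0 genes (1192 at unadjusted p under 0.05), DESeq2 0 and limma with library weights 0.

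Whether history changed the challenge response was tested by the interaction, (CC minus CS) minus (SC minus SS). In D1 the smallest p belonged to Clec2e (-3.91 ± 0.76), the nucleotide receptor gene P2ry14 (-1.97 ± 0.43) and Otud7a (-1.65 ± 0.36), each with adjusted p = 0.0527. Ribosomal protein genes (86 measured, median 1.53 against 0.23, adjusted p = 2e-16; 80 higher adjusted over the list alone) and respiratory chain genes (84 measured, 1.11, adjusted p = 8.68e-11; 60 higher adjusted over the list alone) passed as lists, with 0 among all genes and adjusted p = 0.76 with an estimated correlation. edgeR called 0 genes (6936 at unadjusted p under 0.05), while DESeq2 called 2939 and limma with library weights 17. In D2 Plcd3 (-5.95 ± 1.37) and Atf5 (-5.21 ± 1.16) had adjusted p = 0.453. Ribosomal protein genes (87 measured, median 0.51 against 0.10, adjusted p = 4.03e-08), rapid immediate early genes (21 measured, -0.41, adjusted p = 0.00628) and clock genes (17 measured, -0.33, adjusted p = 8.34e-06; 1 lower adjusted over the list alone) passed as lists. They had adjusted p = 0.415, 0.415 and 0.294 with an estimated correlation. edgeR called 0 genes (2146 at unadjusted p under 0.05), DESeq2 0 and limma with library weights 181. Across genes the challenge responses with and without history had r = 0.344 in D1 (37721 genes, permutation p = 0.624) and -0.163 in D2 (36090 genes, permutation p = 0.386). In D1 38 genes were higher in both responses, where independent lists would share 303, and 0 were lower in both.

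**Figure D5:**
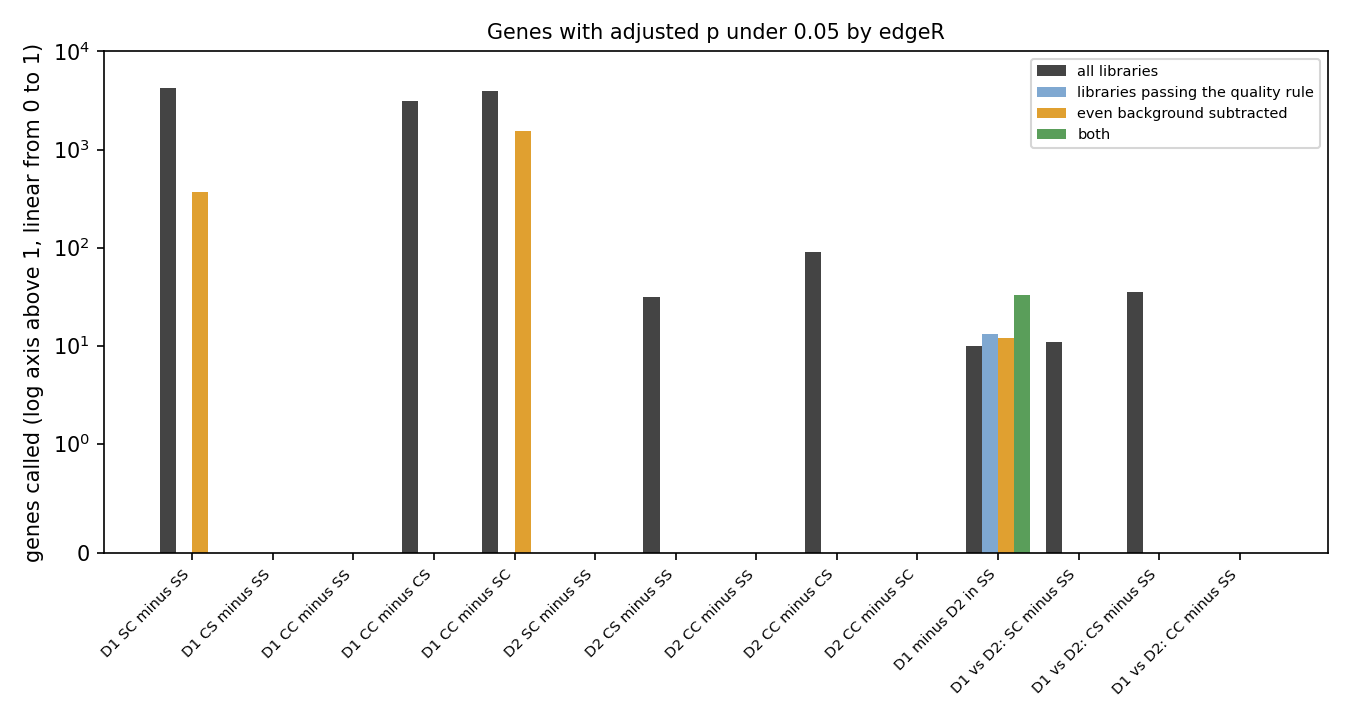
Genes with adjusted p under 0.05 by edgeR (y axis, log scale above 1) in each comparison (x axis) with all libraries, with libraries passing the quality rule, with the background subtracted, and with both. Of the comparisons with treatment, those that called genes with all libraries called 0 with libraries passing the quality rule.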

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

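Of the tests in this part, those chosen only after the result was seen were the weighing of D1 SC minus SS by its count without failing libraries (a count fixed in advance) and by random counterparts of it, the r of changes with the background subtracted, the relation of depth to the background share, and every test on the libraries labelled D1 that lie on the D2 side. Among 104 tests of single libraries against their group, 10 stood apart, and chance puts about 1 in 20 groups there. D2_CC 10 stood apart with a log10 total count of 4.30 and D2_SS 9 with a background share of 5.28% (95% interval 5.08 to 5.48). D1_CS 3 had a background share of 10.0% (9.80 to 10.3). D1_CS 4 had a log2 ratio of Drd1 to Drd2 of -3.46 and a Drd2 level, as log2(CPM + 1), of 8.86. D2_CC 10 held 0 counts of Tac1, 0 of Fos and 0 of Npas4, where its depth allows up to 151 CPM for a count of 0, and D2_CS 9 held 0 of Egr1, where its depth allows 150. D2_SS 4 had Npas4 at 2.41 as log2(CPM + 1). The D1 and D2 changes differed for SC minus SS in 11 genes and for CS minus SS in 35, by the test of the difference.

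Genes of silent families carried reads, and their density, if even over all genes, would account for a large part of many libraries (in the libraries with the most such reads it ran from 0.486 to 0.736 by autosome, against 0.659 over all autosomes). In the libraries with the most such reads, silent genes on X, present once in male mice, held 0.485 (0.450 to 0.517) of the read density of silent autosomal genes, which is consistent with genomic DNA in the libraries, although even transcription of every copy would also follow the single X. Low-level transcription of the whole genome cannot be told apart here, since silent genes near densely transcribed genes held slightly more reads (rho = 0.215 across genes), between the values that would favour or exclude it. Shallow sequencing is argued against, since the share rose with depth in D1 (rho = 0.402, permutation p = 0.0147, adjusted p = 0.0184 over 5 relations). No biological explanation was tested for this pattern.

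The 4277 genes called in D1 SC minus SS were weighed against the lower background of D1_SC and its failing libraries. These explanations overlap. The failing D1_SC 1, 4, 5 and 9 had background shares of 27.0%, 5.54%, 13.2% and 5.79%, and the passing D1_SC libraries 7.88% to 58.3%. D1_SC 4, with 11543108 counts, failed only by its correlation with the other libraries. Without the libraries that failed the quality rule, 4 of them D1_SC, 0 genes were called, as few as in 1 of 60 ways of leaving out 4 D1_SC libraries with the 5 failing ones of other groups, the real one (the others gave 18 to 18502, median 3602), so those libraries may account for the calls (Nr4a3 went from 1.55, adjusted p = 0.00577, to 1.39, adjusted p = 0.189). The difference in background cannot be told apart: slopes on the share in 53 other libraries gave the direction of 71.9% of the genes. They gave a median size of 0.23 where 1.13 was fitted. The slopes used log2(CPM + 1) without TMM scaling and the fit used TMM scaling. These directions and sizes are therefore not on the same scale, and the gap in size does not measure how much the background explains. With the share as a covariate 23 genes were called, and with the background subtracted 373. A response to cocaine that does not depend on history cannot be told apart either, since over 3635 of the genes the subtracted changes had r = 0.0363 with those of CC minus CS, over all genes r = 0.222, and shuffled labels gave r from -0.599 to 0.581. A response that only mice without a cocaine history show stays open and untested.

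Of the libraries labelled D1, 3 with over 1000000 counts lay on the D2 side of the Drd1 to Drd2 midpoint: D1_CC 4 and 9 and D1_CS 4 held 718 (703 to 733), 576 (565 to 587) and 465 (455 to 475) CPM of Drd2 and 44.8, 28.2 and 42.2 of Drd1. Even background is argued against by Drd2 at 16.5 times its level or more, and a swap between a D1 and a D2 group by 0 libraries labelled D2 with more Drd1 than Drd2. For D1_CC 4 and 9 a single wrong label is a candidate explanation: the genes beside Drd1 stood at 1.90 and 1.39 times the background and those beside Drd2 at 6.18 and 5.16, inside the D2_SS ranges and outside those of D1_SS, and the other markers at -2.63 and -2.71, inside the D2 range of -4.36 to -0.665, although D1_CC 7, on the D1 side, also fell outside the D1_SS ranges (4.04 and 3.59) with markers at -1.20. For D1_CS 4 a wrong label cannot be told apart. Its genes beside Drd1 stood at 4.88 (4.58 to 5.18), over the lowest D1_SS library at 4.59 but under the highest D2_CS library at 5.54. That library, D2_CS 5, had a background share of 17.3%, against 53.5% in D1_CS 4. At shares nearer to the latter, D2_SC 5 (52.5%) and D2_CC 4 (56.6%) stood at 1.87 and 1.68, and D1_CC 2 (54.2%) and D1_CC 5 (54.5%) at 4.25 and 5.19. The genes beside Drd2 in D1_CS 4 stood at 6.65 (6.42 to 6.88) and its markers at -1.61. At a like share its genes beside Drd1 therefore lay with the D1 line and those beside Drd2 with the D2 line. A mixture with 50% or more D1 nuclei cannot be told apart, since 0 of the 3 reached 50% of the D1_SS median of Drd1 over the background but neither did D1_SS 8 and 9 (15.4 and 20.2 CPM against a median of 134), and neither an animal with both Cre lines nor a biological explanation was tested.

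The treatment labels were drawn again for each comparison, 60 splits within a line and 40 across lines with the real one included. For D1 SC minus SS 1 of 60 splits, the real one, gave 4277 genes, and the highest other gave 475. For D1 minus D2 in SS 1 of 40, the real one, gave 10, and the highest other gave 0. Chance is unlikely for each taken alone. These are the smallest shares the splits can give, and they were not adjusted over the comparisons. A draw as uneven in background share as D1_SC and D1_SS (exact permutation p = 0.00548) could be missing from 60 splits. Chance is therefore not excluded for D1 SC minus SS. Nor is it excluded for D1 CC minus CS (3134 genes, 9 of 60 splits with as many, highest other 9644), D1 CC minus SC (3955, 5 of 60, 7025), D2 CS minus SS (31, 18 of 60, 2405) or D2 CC minus CS (91, 7 of 60, 11038). Nor can it for the D1 against D2 differences for SC (11, 8 of 40, highest other 26) and CS (35, 4 of 40, 59). For the 8 comparisons with 0 genes every split gave as many (60 of 60, or 40 of 40 for the CC difference). A real count of 0 fixes this in advance, so the splits decide nothing for these comparisons. Their highest others were 921 for D1 CS minus SS, 4873 for D1 CC minus SS, 1366 for the D1 interaction, 1 for D2 SC minus SS, 0 for D2 CC minus SS, 5395 for D2 CC minus SC, 1577 for the D2 interaction and 1 for the CC difference. Splits that call many more genes than the real labels, as in D2 CC minus CS, point to a structure of the samples that the treatment labels do not give.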

How the results depend on the processing

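Chosen only after the data were seen were the background subtraction, its share as a covariate, the subtraction without failing libraries, the fit without the 4 libraries whose receptor region ratio lay on the D2 side, the list tests without failing libraries or with the subtraction, the agreement tests with the subtraction, and each library left out in turn. Unless a construction is named, the cause of a change was not tested. The D1 minus D2 comparison in SS kept most of its genes: 10 of its 10 were called again by DESeq2 (14 called), with no filter on low counts (14), with 2 surrogate variables (16), with limma (101), without failing libraries (13), in a fit of the compared groups (21), with the covariate (12), with the subtraction without failing libraries (33) and without the 4 libraries (10). With the replicate block (8 called) and the subtraction (12) 8 of the 10 were called again, and with RLE scaling (6) 5 were. Depth limits what 3 libraries of D2_CC and D2_CS can show, which held 19825, 19980 and 26297 counts.

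Without failing libraries, which also leaves fewer samples, 0 genes were called for D1 SC minus SS, D1 CC minus CS, D1 CC minus SC, D2 CS minus SS, D2 CC minus CS and the D1 against D2 differences for SC and CS. Of 89 named genes that passed, 6 still did, 77 kept their direction only and 6 reversed: Guca2b in D1 SC minus SS (-0.50) and D1 CC minus SC (0.18), Hoxc12 in D2 CS minus SS (-0.15), D2 CC minus CS (1.06) and the CS difference (0.18), and Plcd3 in D2 CC minus CS (0.17), whose counts came from libraries left out. With the background subtracted the counts were 373, 0, 1559, 0, 0, 0 and 0 in the same order, and with both changes 0 in each of the 7, with 33 for D1 minus D2 in SS. With both, Guca2b turned to -1.07, 0.49 and -0.48 (SC minus SS, CC minus SC, and the SC difference), Hoxc13 to -2.13 in D2 CS minus SS and Plcd3 to 0.53 in D2 CC minus CS. With the share as a covariate D1 SC minus SS gave 23, D1 CC minus CS 0, the D1 interaction 3260 and D2 CS minus SS 59. Without the 4 libraries D1 CC minus SC gave 1957 (1921 shared) and the CS difference 23 (21 shared), and the other 8 counts tested stayed within 1.5 times.

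With DESeq2 D1 CC minus SC gave 7575, the D1 interaction 2939, D2 CS minus SS 2, D2 CC minus CS 23, the SC difference 0 and the CS difference 3. Guca2b turned to -0.34 (D1 SC minus SS), 0.00599 (D1 CC minus SC) and -0.72 (SC difference), Plcd3 to -0.0249 (D2 CS minus SS), 0.30 (D2 CC minus CS) and 0.0854 (CS difference), and Wfdc18 to 0.24 (CS difference). With RLE scaling D1 CC minus CS gave 674, the D1 interaction 1193, D2 CS minus SS 6, D2 CC minus CS 6, D1 minus D2 in SS 6, the SC difference 1 and the CS difference 7. RLE moved the median of all genes by -0.19 for D1 SC minus SS, 0.15 for D1 CS minus SS, -0.17 for D1 CC minus CS, 0.15 for D1 CC minus SC, -0.17 for D2 SC minus SS, 0.12 for D2 CC minus CS, 0.18 for D2 CC minus SC, 0.29 for the D2 interaction, -0.25 for the SC difference and 0.30 for the CS difference. With no filter D2 CS minus SS gave 104, D2 CC minus CS 145, the CS difference 55 and the CC difference 1. With 2 surrogate variables D1 CC minus CS gave 0, D1 CC minus SC 9062, the D1 interaction 3197, D2 CS minus SS 0, D2 CC minus CS 0, D1 minus D2 in SS 16, the SC difference 1 and the CS difference 3. A fit of the compared groups alone gave 0 for D1 CC minus CS, D2 CS minus SS, D2 CC minus CS and the SC and CS differences, 224 for D1 CC minus SC and 21 for D1 minus D2 in SS. It was not run for the interactions, which use every group.

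With limma and library weights D1 SC minus SS gave 2736, D1 CS minus SS 16547, D1 CC minus SS 48, D1 CC minus SC 17029, the D1 interaction 17, D2 SC minus SS 4892, D2 CS minus SS 4155, D2 CC minus SS 8423, D2 CC minus CS 0, the D2 interaction 181, D1 minus D2 in SS 101, the CS difference 0 and the CC difference 19. It reversed Guca2b (-0.84 in D1 SC minus SS, 0.79 in D1 CC minus SC, -0.92 in the SC difference), Hepacam (-0.0159 in D1 SC minus SS), Actg1 (-0.11), Hsp90aa1 (-0.26) and Npy (-0.16) in D1 CC minus SC, Nfkbia (-0.66 in D2 CS minus SS, 0.19 in the CS difference), and Kcnd1 (0.0739), Kmt2b (0.11), Hoxc12 (0.19) and Wfdc18 (0.0659) in D2 CC minus CS. Replicate numbers were tested as a block. Deviations of same-numbered libraries had a mean r of 0.00102 over 49 pairs in D1 and 0.0649 over 48 in D2, and 5 of 36 and 3 of 35 libraries were closest to their own number, so these data show no pairing by number. With the block D1 SC minus SS gave 1880, D1 CC minus SC 1469 and D2 CS minus SS, D2 CC minus CS and the SC and CS differences 0 each.

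Of 197 lists called with the preset correlation, 8 were with the estimated one; with RLE scaling 186 were (173 of them shared), without failing libraries 180 (151), with the subtraction 134 (121) and with both 134 (114). The r of D1 and D2 changes for CS minus SS turned to 0.0431 without failing libraries, 0.0746 with the subtraction and 0.151 with both. That of the challenge responses in D2 turned to 0.133, 0.0331 and 0.391. For CC minus SS it was -0.511 without failing libraries and -0.570 with the subtraction (permutation p = 0.0198 and 0.0099, the latter the smallest 100 shuffles can give), and -0.508 with both (permutation p = 0.0594).

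Leaving out 1 library gave 459 to 10348 genes for D1 SC minus SS, 0 to 5700 for D1 CC minus CS, 683 to 8900 for D1 CC minus SC, 0 to 2517 for the D1 interaction, 6 to 200 for D2 CS minus SS and 6 to 364 for D2 CC minus CS. It gave 0 to 0 for D1 CS minus SS and CC minus SS and for D2 SC minus SS, CC minus SS, CC minus SC and the interaction. For D1 SC minus SS the count was 6928 without CC 3, 1509 without CS 5, 459 without SC 2, 511 without SC 4, 1563 without SC 5, 10348 without SC 6, 7435 without SC 7, 777 without SC 9 and 1505 without SS 3. For D1 CC minus CS it was 0 without CC 1 or CC 3, 1567 without CS 1, 1025 without CS 2, 5700 without CS 3, 1449 without CS 7, 2062 without CS 8 and 4710 without SC 5. For D1 CC minus SC it was 8900 without CC 3, 2013 without CS 5, 683 without SC 2, 831 without SC 4, 2160 without SC 5, 8742 without SC 6, 7769 without SC 7, 1390 without SC 9 and 2075 without SS 3. The D1 interaction gave 687 without CC 5, 773 without CC 6, 1002 without CC 8, 664 without CC 9, 800 without SC 6, 2517 without SC 7, 1431 without SC 8, 983 without SS 8, 1144 without SS 9 and 793 without SS 10. D2 CS minus SS gave 200 without CS 1, 137 without CS 2, 84 without CS 3, 6 without CS 4, 141 without CS 5, 160 without CS 7, 175 without CS 8, 179 without CS 10, 58 without SC 3, 9 without SS 1, 16 without SS 4, 12 without SS 8, 20 without SS 9, and 8 without SS 2, 3, 5, 6 or 7. D2 CC minus CS gave 9 without CC 1, 7 without CC 2, 6 without CC 4 or CC 8, 8 without CC 5 or CC 6, 10 without CC 7 or CC 9, 40 without CC 10, 257 without CS 1, 251 without CS 2, 9 without CS 4, 212 without CS 5, 293 without CS 7, 364 without CS 8 and 327 without CS 10.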

Other observations

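The tests on genes beside the receptor genes were chosen only after the result was seen, while the list tests of this part were fixed in advance. Subunits of GABA-A receptors, the main inhibitory receptors, were higher as a list in D1 SC minus SS (14 measured, median 0.27 against -0.21, adjusted p = 0.00321; adjusted p = 0.404 with an estimated correlation), with 5 higher among all genes and 6 higher and 1 lower adjusted over the list alone. They were higher in D1 CC minus CS too (median 0.27 against -0.09, adjusted p = 0.00136; adjusted p = 0.327 with an estimated correlation), with 2 among all genes and 5 adjusted over the list alone. Genes that respond to glucocorticoids were higher as a list in D1 CC minus SS (13 measured, 12 above 0, median 0.24 against -0.04, adjusted p = 0.00543; adjusted p = 0.268 with an estimated correlation), with 0 among all genes and 1 adjusted over the list alone. In the D2 interaction markers of oligodendrocytes (10 measured, 10 below 0, median -0.61 against 0.10, adjusted p = 6.53e-05), astrocytes (10 measured, 9 below 0, -0.56, adjusted p = 0.00151) and vascular cells (7 measured, 7 below 0, -0.72, adjusted p = 0.0147) were lower as lists, with adjusted p = 0.294, 0.294 and 0.415 with an estimated correlation. Markers of microglia and of interneurons passed in 0 of the 16 comparisons with the preset correlation; their smallest adjusted p were 0.0568 and 0.0662.

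The genes beside Drd1 were higher in D1_SS than in D2_SS by similar log2 changes, from 1.63 to 1.70 for the 5 that passed, and Ankk1 and Ttc12 beside Drd2 were higher in D2_SS. A candidate explanation is that the Cre lines carry extra copies of the DNA around the receptor gene, as a transgene built from a long piece of genomic DNA would, and that these copies are read with the even background. If so, the reads of the 4 unnamed genes past their D2_SS level should rise with the background share across D1 libraries, at a steady ratio to the background, and if they were transcribed with Drd1 they should follow Drd1. Across all 36 D1 libraries with over 1000000 counts, their CPM with the D2_SS level subtracted rose with the share (rho = 0.501, permutation p = 0.0022, adjusted p = 0.00352 over 8 relations; r = 0.335, adjusted p = 0.0627, or 0.297 without the 2 farthest). Leaving out the 4 libraries with a ratio on the D2 side, which were picked by these same genes, gave rho = 0.702. The ratio to the background was not steady: it fell as the share rose (rho = -0.640, permutation p = 0.0003, adjusted p = 6e-04), with medians of 8.84 in D1_SC and 4.77 in D1_CS. The background is the divisor of this ratio, and in the D2 line it also differed with the share. It was 4.31 in D2_SS 9 (share 5.28%) and 1.47 in D2_SS 7 (60.3%). Its fall therefore does not count against extra copies. Against Drd1 over the background the subtracted CPM had rho = -0.143 (permutation p = 0.410; r = -0.0881, or 0.110 without the 2 farthest). Neither explanation can be told apart from the other, since the fall of the ratio decides nothing and the relation to Drd1 turned without the 2 farthest libraries. Were there extra copies, the line differences of Sfxn1, Ankk1 and Ttc12, and a part of those of Drd1 and Drd2, could be DNA and not RNA.

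D1_CC 10 passed the quality rule with 24520138 counts, yet its genes beside Drd1 stood at 2.42 times the background (2.24 to 2.60) and those beside Drd2 at 4.82 (4.65 to 4.99), the first under the lowest D1_SS library, 4.59, and inside the D2_SS range of 1.25 to 4.31, the second over the highest D1_SS library, 2.47, and just under the lowest D2_SS library, 4.91. Its score of the other markers was -0.815, inside the D2 range, as were those of D1_CC 7 (-1.20) and D1_SC 1 (-0.745), whose region ratio lay on the D1 side, and of D1_SC 5 (-1.12), with too few counts there to read.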
